A study of Mus musculus with 9 samples.

How the data were processed

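Per the labels, RNA was extracted from 3 libraries each of mouse astroglia (AG), brainstem tumour cells (BS) and olfactory bulb tumour cells (OB), made into libraries with a stranded TruSeq kit and sequenced on a HiSeq3000. The submitters' processing notes name bcl2fastq 1.8.4, HISAT2 2.1.0, featureCounts of Subread 1.6.2, DESeq2 1.20.0 and the mouse build mm9, without their role or order. The annotation, the strand setting and the treatment of reads shared by several transcripts are not given in the sources used here.

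The deposited table holds signal values for 16260 RefSeq transcripts in 9 libraries. Each value is a number of reads divided by 1 size factor per library: 100.0% of values were whole reads within a tolerance of 0.05 reads once the factor was undone, so that whole reads could be recovered. Size factors ran from 0.905 to 1.20. Transcripts were named from a RefSeq table (16202) or a GENCODE table (41), and 17 without a name were left out of the tests. Values of transcripts with the same symbol were added, which gave 14771 named genes, of which 1284 had more than 1 transcript in the table. The median row value was 258.6 for genes with 1 RefSeq transcript, 12.57 for genes with 2 and 6.815 for genes with 3 or more. Gapdh, with 2 RefSeq transcripts, ranged from 0.985 to 5.84. Reads shared by several transcripts therefore appear to be missing, and low values of such genes are not read as low expression. No positions are given, since the reference at hand is of another build than the table.

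The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean for each of the 3 groups in 1 fit of all 9 libraries, a trend in the moderated variance, two-sided tests and Benjamini-Hochberg adjustment within each of 4 comparisons. Genes were kept that reached 10 normalized reads in at least 3 libraries (10576 genes), and a gene was called at an adjusted p under 0.05. The comparisons were OB with AG, BS with AG, OB with BS, and the mean of both tumour groups with AG. Of 31 gene lists written from textbook knowledge, 29 were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera was repeated with an estimated correlation and beside the rotation test fry. A list of sex-linked genes was used only as a check of the libraries, and the erythroid list had 0 members in the table. The tests, the lists and most alternatives were chosen before the data were examined.

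Genes were named by a rule fixed with them: the genes of the genotype labels, the 10 largest changes in each direction among called genes with a mean of at least 50 normalized reads in the higher group and no overlap between groups, leaving out clone names and sex-linked genes, and up to 4 called genes of each list. Not every gene that the rule picked is given. Genes with 0 reads in a group were given a lower bound against a floor of 3 reads per library, equal to a normalized value of 2.91 in AG, 2.89 in BS and 3.14 in OB. Genes with 1 to 3 reads were given the ratio of reads with an exact (Clopper-Pearson) 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

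The overlap of the comparisons with AG was set beside independent lists and beside 50 simulations of unchanged groups that share the AG libraries. Alternatives were pseudocounts, filters, rescaling, quantile normalization, fits of the compared groups only, variance without a trend or with a robust trend, minimum changes, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the number in the titles as a block, and each library left out in turn. Alternatives added after the data were seen are named in the closing part. A pair of numbers recurs in the titles of both tumour groups (BS_287 with OB_287, BS_295 with OB_295), and the labels do not say what they mark.

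The method was tested on simulated reads with the spread of these libraries, 200 genes changed in each of 5 draws. limma called 76.4% of 8-fold changes in OB against AG, 74% in BS against AG and 73.6% in OB against BS, and 2.8%, 4.8% and 6.8% of 2-fold changes. Unchanged genes made up 10.77%, 10.24% and 22.8% of the calls, above the nominal 5%, because tumour libraries vary more than AG libraries and the fit shares 1 spread: with 1 simulated spread for all groups the share was 5.58% in OB against AG and 6.84% in OB against BS. With the spread of each group, a fit of the compared groups alone lowered the share in OB against BS to 6.12%, from 23.68% in the matching fit of 3 groups, and called 50.4% of 8-fold changes in place of 75.6%. In OB against AG it raised the share to 18.1%, from 8.73%. Of 20 simulated lists raised 2-fold camera called 20, and of 20 unchanged lists 0. Their genes were drawn independently, for OB against AG only, so that lists whose genes vary together were not tested. In the data the estimated correlation was 0.575 for oligodendrocyte precursor genes. Figures were drawn with matplotlib 3.10.9.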

Results

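Messenger RNA was sequenced from 9 mouse libraries in 3 groups of 3. One group came from astroglia (AG), brain cells of the C57BL/6 strain whose genotype label names p53 DN and an Nf1 shRNA. The others came from tumour cells of the brainstem (BS) and of the olfactory bulb (OB), in mice of mixed 129 and C57BL/6 background that overexpressed Foxr2, a forkhead transcription factor, and carried a p53 cko allele. The series title describes profiling of brain tumours induced by Foxr2. The libraries are titled AG_1, AG_2, AG_3, BS_287, BS_295, BS_296, OB_257, OB_287 and OB_295. Strain, genotype and any culture history differ together between AG and the tumour cells, so that no comparison against AG separates them. The labels do not say whether the libraries of a group came from separate animals or cultures, and p-values measure the spread between these samples, which may be technical.

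The table held between 11300273 and 19868282 reads per library, from 14987773 to 19868282 in AG, 12680832 to 15282668 in BS and 11300273 to 13927771 in OB. Values below are normalized reads, given as mean ± SD over 3 libraries, and changes are on the scale of log2(normalized reads + 1), which understates the change of low genes. A gene at 0 reads in a group is given a lower bound for its fold against 3 reads per library, and a gene with 1 to 3 reads a ratio with its 95% counting interval, which covers counting error only. Genes with several annotated RefSeq transcripts had low values in this table, so levels are best compared between libraries and not between genes. Where several libraries are named as left out, each was left out on its own unless both are said to be. The median row value was 258.6 for genes with 1 transcript and 12.57 for genes with 2.

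The AG libraries lay close together and far from every tumour library. Correlations of log2 values across 10576 genes ran from 0.992 to 0.993 within AG, from 0.705 to 0.741 between AG and tumour libraries, and from 0.841 to 0.959 among the 6 tumour libraries. The median SD of a gene between libraries was 0.12 in AG, 0.47 in BS and 0.48 in OB on the log2 scale. The first principal component held 65.2% of the variance and parted AG from the tumours. The second, with 14.6%, set OB_257 apart, and the third, with 9.97%, set BS_287 apart. The tumour libraries did not part by site on these components. On the fourth, with 3.6%, BS_295 and BS_296 (39.2 and 32.1) lay opposite OB_287 and OB_295 (-42.4 and -43.2). BS_287 (1.15) and OB_257 (13.9) lay between them. BS_287 correlated best with OB_287 (0.919), and the highest correlation between tumour libraries was that of BS_295 and BS_296 (0.959).

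**Figure D1:**
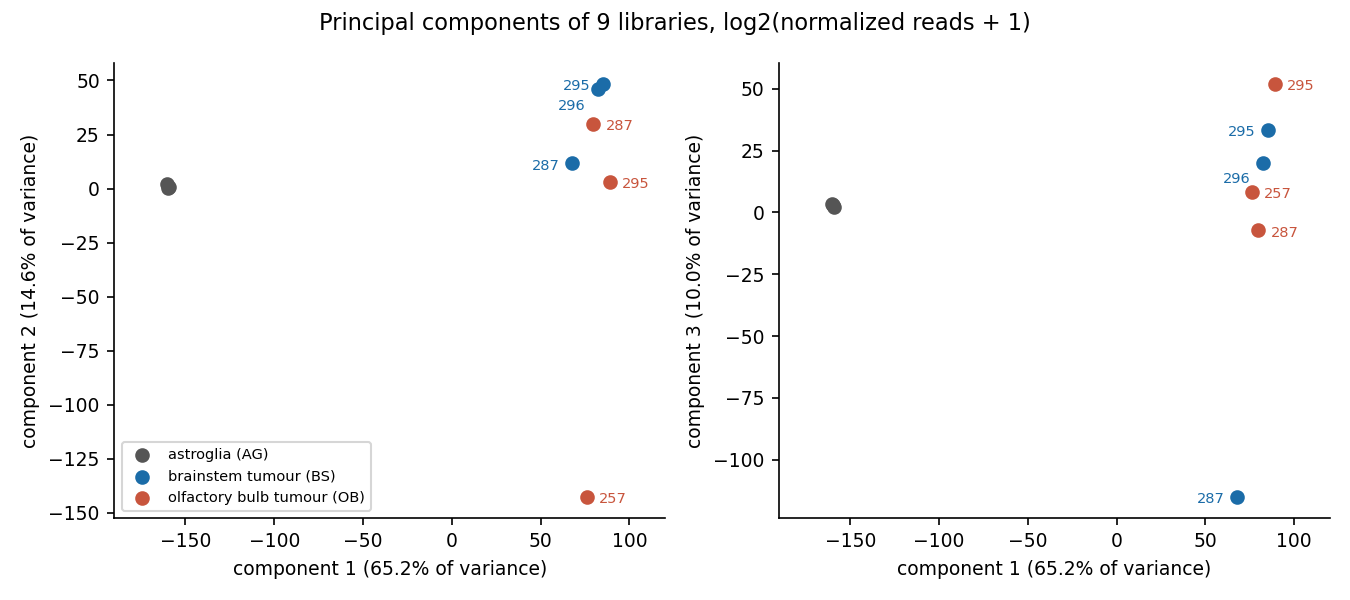
Each point is one library, on component 1 (65.2% of the variance) against component 2 (left, 14.6%) and component 3 (right, 9.97%), computed from log2(normalized reads + 1) of 10576 genes, with the library number beside each tumour library. The 3 AG points overlap on the left, OB_257 lies apart on component 2 and BS_287 on component 3.

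The genes named in the genotype labels were read first. Foxr2 had 1 read in all 3 AG libraries together, against 9526 ± 2707 normalized reads in BS and 5763 ± 1168 in OB. The ratio to AG was 30541-fold (counting interval 5481 to 1206300.0) in BS and 18222-fold (counting interval 3270.0 to 719760.0) in OB, with a limma adjusted p of 6.26e-07 in both comparisons. Foxr2 in OB differed from BS by -0.71 ± 0.34 (SE) on the log2 scale, which did not pass the test (limma adjusted p = 0.549). Nf1, a negative regulator of RAS, stood at 1464 ± 127 in AG, 5309 ± 830.3 in BS and 5823 ± 2434 in OB, higher in BS by 1.85 (limma adjusted p = 0.00109) and in OB by 1.92 (limma adjusted p = 0.000886). The genotype label of AG names an Nf1 shRNA, so that this difference is not read as a rise in the tumour cells. Trp53, the gene of p53, had 27.3 ± 6.55 in AG, 27.7 ± 8.79 in BS and 33.5 ± 16.9 in OB, with limma adjusted p of 0.992 and 0.786 against AG. Trp53 has 2 annotated transcripts and few reads here. Its value checks neither a deleted part of the gene nor an altered protein.

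**Figure D2:**
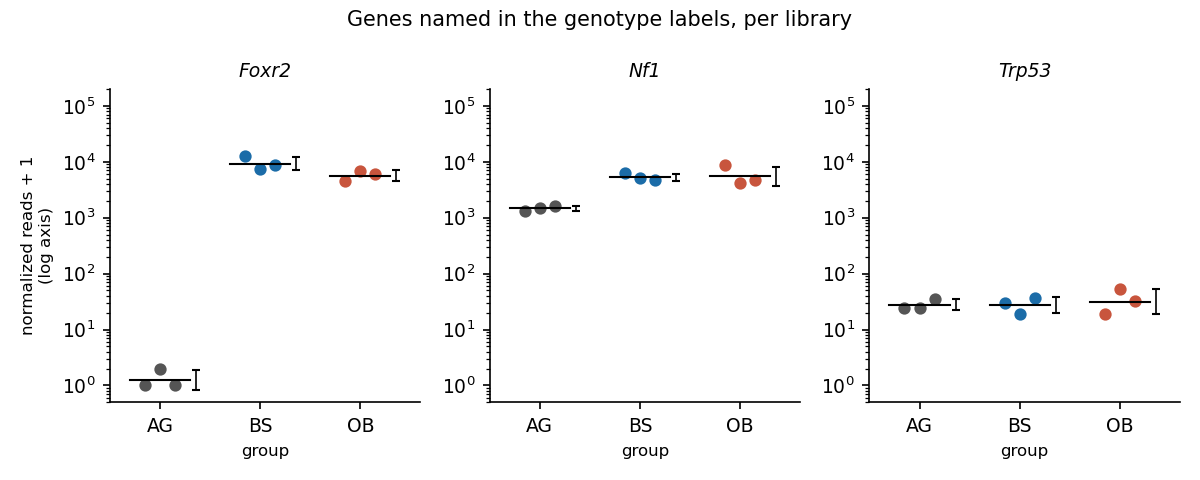
Normalized reads plus 1 on a log axis for Foxr2, Nf1 and Trp53, with one point per library in AG, BS and OB. Horizontal lines are group means of log2 values and bars their SD (n = 3); Foxr2 lies at 0 or 1 normalized reads in AG and between 4505 and 12567 in the tumour libraries.

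The comparison of olfactory bulb tumour cells with astroglia asks how the Foxr2-overexpressing tumour cells of 1 site differ from the AG cells. OB cells expressed genes of the oligodendrocyte lineage that had few or 0 reads in AG. Olig2, a basic helix-loop-helix factor of oligodendrocyte and motor neuron progenitors, had 0 reads in AG and 12141 ± 8478 normalized reads in OB, at least 4174-fold higher. Olig1, its neighbour in function, was 23349-fold (counting interval 6463 to 192810.0) higher, and Sox10, a regulator of oligodendrocyte fate, rose from 1.33 ± 0.736 to 15186 ± 14460.1. Of the brain proteoglycan genes, Bcan was 9372-fold (counting interval 3207 to 45449) higher and Ncan rose by 11.28 on the log2 scale. Matrix and cytoskeletal genes of mesenchymal cells went the other way: Acta2, smooth muscle actin, fell from 53782 ± 1881 in AG to 44 ± 34.8 in OB, and the calcium-binding protein gene S100a6 from 64510.1 ± 3467 to 28 ± 34.5.

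Besides Foxr2, Olig2, Olig1, Bcan, Ncan and Sox10, the largest increases in OB were those of Gpr17, a receptor of differentiating oligodendrocyte precursors, at 8251-fold (counting interval 2823 to 40012), the connexin gene Gjc3, at 8229-fold (counting interval 2815 to 39905), the potassium channel gene Kcna2, at least 1612-fold, and the protocadherin gene Pcdh17, at least 1089.8-fold. The limma adjusted p of these 4 genes ran from 3.44e-05 for Kcna2 to 0.0124 for Gjc3. Levels of such genes varied widely between OB libraries: Sox10 had 30528 normalized reads in OB_257, 1808 in OB_287 and 13223 in OB_295. Among the largest decreases besides S100a6 and Acta2 were those of Arhgef5, which had 0 reads in OB and 3273 ± 38.3 in AG, and of Loxl1, Itih2, Ppl, Inhba, Anxa3 and Pax8. Inhba, an activin subunit, went from 4155 ± 298 to 1.32 ± 1.44. Pax8, a factor of the midbrain-hindbrain region, went from 3761 ± 198 to 2.22 ± 3.85.

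Of 14 tested oligodendrocyte precursor genes, 12 rose and 0 fell in OB (12 adjusted over the list alone), with a median log2 change of 7.96, or 7.38 with genes at 0 reads set at their bound. Pdgfra and Vcan, named here after their values were seen, did not pass. The list was called higher by camera (adjusted p = 2.62e-07, and adjusted p = 0.366 with an estimated correlation). All 4 tested markers of human FOXR2-activated neuroblastoma, Foxr2, Olig2, Sox10 and the synaptic vesicle gene Syp, rose (camera adjusted p = 0.000141, and adjusted p = 0.0709 with an estimated correlation). Foxr2 is set by the genotype, and without it the list was still called (camera adjusted p = 0.00431, and adjusted p = 0.139 with an estimated correlation). Of 8 mature oligodendrocyte genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.399 with an estimated correlation). Cldn11, a myelin tight junction gene, was at least 1667-fold higher, the myelin regulator Myrf rose by 8.73, and Cnp and Enpp6 rose too, while Aspa fell. Without OB_257 this list was no longer called (camera adjusted p = 0.139), and Enpp6 was not called without AG_1, AG_2 or AG_3.

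A part of the neural stem, neuronal and Notch genes also rose. Of 16 stem and progenitor genes 9 rose and 0 fell, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.531 with an estimated correlation). They included Fabp7, a fatty acid binding protein of radial glia (18798 ± 19405 in OB against 18.6 ± 3.56 in AG), Hes5 and Nr2e1. Of 11 neuronal genes 6 rose and 0 fell, and 7 rose adjusted over the list alone (camera adjusted p = 0.00199, and adjusted p = 0.166 with an estimated correlation), led by Elavl3, an RNA-binding protein of neurons (1779.5 ± 1070.3 against 4.1 ± 2.94), Stmn3, Dner and Syp. Of 10 Notch response genes 5 rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.471 with an estimated correlation). Dll1, a Notch ligand, rose by 7.34 and Notch3 by 5.60. Hes1, Hey1, Hey2, Dtx4 and Dll3, named here after their values were seen, did not pass over all genes. Hes1 had 23.2 normalized reads in OB_257, 793.7 in OB_287 and 328.2 in OB_295, against 1484 to 1517.5 in AG. Without OB_287 the Notch list was not called. Astrocyte genes were divided: 6 of 12 rose, among them Atp1b2, Aldoc and S100b, while Gja1, the main astrocyte connexin, and Clu fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0473, and adjusted p = 0.547 with an estimated correlation). S100b was not called without AG_1, AG_2, AG_3, OB_257 or OB_295, and Gja1 neither without AG_1, AG_2 or AG_3 nor by edgeR. The call of the astrocyte list ended with a pseudocount of 5, with quantile normalization, with a filter of 50, and without AG_1, OB_287 or OB_295.

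The strongest decreases by list were those of extracellular matrix and cytokine genes. Of 19 matrix and mesenchymal genes 17 fell and 0 rose (17 adjusted over the list alone), with a median log2 change of -7.25 (camera adjusted p = 1.88e-08, and adjusted p = 0.0709 with an estimated correlation). Col1a1, a fibrillar collagen chain, fell from 40954 ± 5404 to 30.1 ± 29.6. Of 13 NF-kB and cytokine genes 12 fell and 0 rose, and 13 fell adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.0842 with an estimated correlation). The chemokine gene Ccl2 went from 3255 ± 145 to 25.1 ± 37, and Lcn2, Cxcl1 and Ccl7 were near 0 in OB. Of 15 p53 target genes 6 fell and 0 rose, and 7 fell adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.24 with an estimated correlation). Ccng1, cyclin G1, fell from 12138 ± 523 to 894 ± 108, and Eda2r, Fas and Pmaip1 fell with it. Pmaip1 was not called by edgeR, nor without AG_1, AG_2, AG_3 or OB_295. Of 16 glycolysis and hypoxia genes 7 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.393 with an estimated correlation), with Tpi1, triosephosphate isomerase, at 4123 ± 323 in OB against 13373 ± 712 in AG. The glycolysis call ended without OB_257.

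The remaining lists were not called by camera in OB against AG. RAS-MAPK response genes had 1 rise and 8 falls among 16 (camera adjusted p = 0.059), Epha2 falling from 7262 ± 424 to 73.5 ± 28.1, and ETS family factors 1 rise and 5 falls among 12 (camera adjusted p = 0.0981). Hedgehog response genes had 2 rises and 3 falls among 8 (camera adjusted p = 0.442), and WNT response genes 3 rises and 1 fall among 7 (camera adjusted p = 0.539). Ventral forebrain genes had 5 rises, with Erbb4 at least 754-fold higher, and 5 falls, with Sp8 and Lhx8, among 14 (camera adjusted p = 0.985). Forebrain patterning genes had 1 rise and 4 falls among 10 (camera adjusted p = 0.223), and hindbrain and Hox genes 1 rise and 4 falls among 11 (camera adjusted p = 0.892), En1 going from 2759 ± 134 to 37.8 ± 63.7, a call that edgeR did not make. Of the cell division lists, DNA replication had 3 falls among 18 (camera adjusted p = 0.442) and mitosis 5 falls among 18 (camera adjusted p = 0.0932), with Mki67 at 12311 ± 6696 against 29949.5 ± 1142, which was not called by edgeR, with quantile normalization or without AG_1, AG_2 or AG_3. MYC-driven nucleolar genes had 1 rise and 2 falls among 23 (camera adjusted p = 0.602), cytosolic ribosomal protein genes 1 rise and 2 falls among 28 (camera adjusted p = 0.192), cholesterol synthesis genes 4 falls among 15 (camera adjusted p = 0.11), interferon and MHC class I genes 2 rises and 3 falls among 12 (camera adjusted p = 0.289), and immediate early genes 5 falls among 11 (camera adjusted p = 0.0553). Some of these lists were called when 1 library was left out: RAS-MAPK without OB_287 (camera adjusted p = 0.0217), interferon without OB_257 (0.0373), mitosis without AG_1, AG_2, AG_3 or OB_287 (0.0385 to 0.0491), and immediate early genes without AG_1, AG_2, AG_3 or OB_295 (0.0212 to 0.0479). Quantile normalization called the ribosomal protein list higher (camera adjusted p = 0.00761).

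Markers of other cell types were few among the genes tested. Of 3 tested microglia markers 0 passed by limma, Cd68 having 38.6 ± 2.39 in AG and 55.8 ± 22.9 in OB (camera adjusted p = 0.985). Of 3 endothelial markers Flt1 fell from 983 ± 63.5 to 0.952 ± 1.65 (camera adjusted p = 0.597). Of 4 pericyte and smooth muscle markers Acta2 and Cnn1 fell and Notch3 rose (camera adjusted p = 0.578). Of 3 ependymal markers Foxj1 and Tmem212 fell (camera adjusted p = 0.0513, and 0.0256 without OB_257).

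In all, limma called 1687 genes higher and 2008 lower in OB among 10576 (3695 in total), 1421 and 1683 of them by at least 2-fold. Upper-quartile rescaling moved the median log2 change of all genes from -0.01 to 0.18 and turned the split to 2158 higher and 1675 lower, so that the balance of rises and falls depends on the scaling. The count was 2086 without AG_1, 2086 without AG_2 and 2098 without AG_3.

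**Figure D3:**
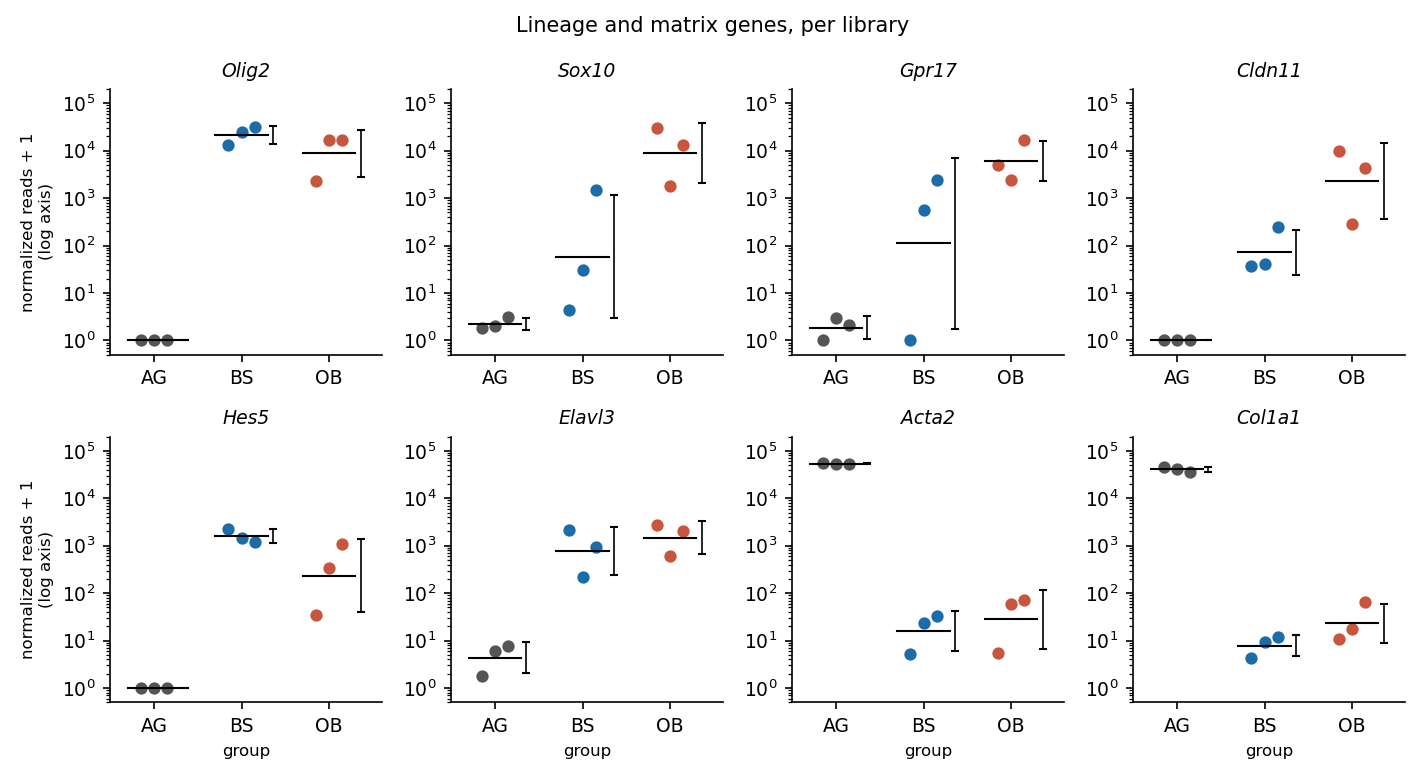
Normalized reads plus 1 on a log axis for 8 genes named in the text, with one point per library in AG, BS and OB. Horizontal lines are group means of log2 values and bars their SD (n = 3); Olig2, Cldn11 and Hes5 are at 0 in every AG library, and Acta2 and Col1a1 are higher in AG than in every tumour library.

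The comparison of brainstem tumour cells with astroglia puts the same question to tumour cells of the other site. Olig1 and Olig2 led again: Olig2 was at least 7962-fold higher (23155 ± 8942 in BS and 0 in AG) and Olig1 47036-fold (counting interval 13021 to 388400.0). Bcan and Ncan rose to 12912 ± 2240.2 and 27181 ± 4807. Lrrn1, a leucine-rich repeat membrane protein gene, was at least 2616-fold higher and Zic1, a zinc-finger factor of the dorsal neural tube and cerebellum, at least 1268-fold, while Fam181b was 5832-fold (counting interval 1614 to 48161) and Lrrc4b 10187-fold (counting interval 1828 to 402390.0) higher. S100a6 fell from 64510.1 ± 3467 in AG to 9.22 ± 15.1 in BS, Acta2 to 19.7 ± 14.4, Col1a1 to 7.58 ± 3.83 and Anxa1, an annexin, from 19923 ± 1020.1 to 8.46 ± 6.62. Itih2 was at least 2317-fold lower, and Col8a1, Anxa3, Arhgef5, Gprc5a and Ppl made up the rest of the largest decreases. The limma adjusted p of these genes ran from 9.65e-07 for Arhgef5 to 0.000369 for Anxa3.

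Of 14 oligodendrocyte precursor genes 9 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 6.55e-07, and adjusted p = 0.348 with an estimated correlation). They included Cspg4, the proteoglycan NG2 (5096 ± 3401 against 9.04 ± 3.12), and Ptprz1. Sox10 did not pass: it had 3.35 normalized reads in BS_287, 29.9 in BS_295 and 1511 in BS_296. The other 3 FOXR2 tumour markers rose, and all 4 when adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.0836 with an estimated correlation). Without Foxr2 the list was still called (camera adjusted p = 0.00928, and adjusted p = 0.161 with an estimated correlation). Of 8 mature oligodendrocyte genes, Cldn11 and Myrf rose and Aspa fell, as they did adjusted over the list alone (camera adjusted p = 0.382). Of 16 stem and progenitor genes 9 rose and 0 fell, and 10 rose adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.366 with an estimated correlation), with Hes5 at least 567-fold higher, Sox3 at least 662-fold and the RNA-binding protein gene Msi1 at 1312 ± 477 against 10.9 ± 4.87. Of 11 neuronal genes 7 rose and 0 fell, over the list alone as well (camera adjusted p = 0.000433, and adjusted p = 0.115 with an estimated correlation). Of 10 Notch response genes 5 rose and 0 fell, over the list alone as well (camera adjusted p = 0.00823, and adjusted p = 0.366 with an estimated correlation). Dll1 stood at 2352 ± 1332 against 7 ± 2.65 in AG. Hes1, Hey1, Hey2, Dtx1 and Dtx4, named here after their values were seen, did not pass. Of 12 astrocyte genes 6 rose, led by Atp1b2, Acsbg1 and Aldoc (Acsbg1 was not called without AG_1, AG_2, AG_3, BS_295 or BS_296), and Clu fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0353, and adjusted p = 0.593 with an estimated correlation). That call ended with a pseudocount of 5, with quantile normalization, with a filter of 50, and without AG_1 or BS_296.

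Of 19 matrix and mesenchymal genes 16 fell and 0 rose, over the list alone as well (camera adjusted p = 5.11e-08, and adjusted p = 0.0836 with an estimated correlation). Of 13 NF-kB and cytokine genes 12 fell and 0 rose, over the list alone as well (camera adjusted p = 1.98e-07, and adjusted p = 0.0836 with an estimated correlation), the prostaglandin synthase gene Ptgs2 going from 5332 ± 342 to 10.4 ± 9.95 and complement C3 from 1327 ± 40.7 to 2.56 ± 3.62. Of 15 p53 targets 6 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00757, and adjusted p = 0.161 with an estimated correlation), with Ccng1 at 727 ± 37.7 and Phlda3 at 124 ± 94.5 against 3539 ± 329.8 in AG. Of 16 glycolysis and hypoxia genes 9 fell and 1 rose, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.325 with an estimated correlation). The 3 tested ependymal markers Foxj1, Tmem212 and Aqp1 fell (camera adjusted p = 0.0181, and adjusted p = 0.161 with an estimated correlation), with a median log2 change of -4.25, or -2.74 with Tmem212 set at its bound. Aqp1 was not called by edgeR, nor without AG_1, AG_2, AG_3, BS_287 or BS_295.

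The other lists were not called in BS against AG. Their camera adjusted p-values were 0.797 for ventral forebrain genes (5 rises and 5 falls among 14), 0.507 for forebrain patterning genes (3 rises and 4 falls among 10), 0.772 for hindbrain and Hox genes (1 rise and 1 fall among 11) and 0.922 for Hedgehog response genes (2 rises and 3 falls among 8). They were 0.516 for RAS-MAPK response genes (3 rises and 4 falls among 16), 0.516 for ETS factors (1 rise and 3 falls among 12) and 0.382 for WNT response genes (4 rises and 1 fall among 7), in which Axin2, a feedback inhibitor of the pathway, reached 4983 ± 4484 against 38.1 ± 3. They were 0.507 for MYC-driven nucleolar genes (3 rises among 23), 0.758 for DNA replication (1 rise and 1 fall among 18), 0.516 for mitosis (1 rise and 3 falls among 18), 0.61 for cholesterol synthesis (1 rise and 3 falls among 15) and 0.507 for ribosomal protein genes (2 falls among 28). They were 0.198 for interferon and MHC class I genes (1 rise and 2 falls among 12), 0.0832 for immediate early genes (5 falls among 11), 0.679 for microglia (1 fall, Tmem119, among 3), 0.516 for endothelial (1 fall, Flt1, among 3) and 0.464 for pericyte markers (1 rise and 2 falls among 4). Leaving out 1 library called the interferon list (without BS_296, camera adjusted p = 0.0259), the ribosomal list (without BS_295, 0.0334) and the immediate early list (without AG_2, AG_3, BS_295 or BS_296, 0.0296 to 0.0429). Quantile normalization called the ribosomal list higher (0.0321).

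In all, 1652 genes were called higher and 2060 lower in BS (3712 in total), 1357 and 1713 of them by at least 2-fold. With upper-quartile rescaling the split was 2135 higher and 1674 lower, with a median log2 change of 0.18 in place of -0.03. The count was 2035 without AG_1, 2001 without AG_2 and 2023 without AG_3.

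**Figure D4:**
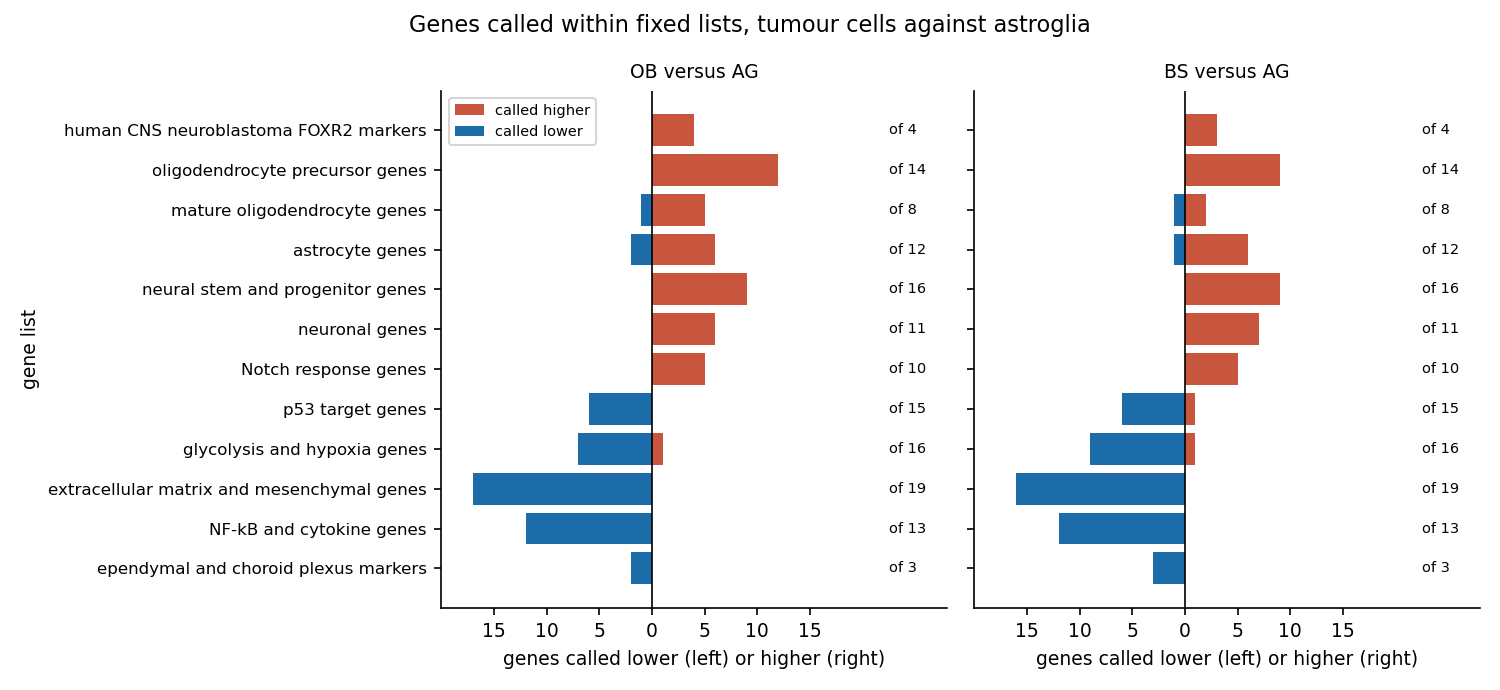
Bars give, for each of 12 gene lists called in at least one comparison with AG, the number of genes called higher (right of 0) or lower (left of 0) in OB (left panel) and in BS (right panel) against AG, with the number tested beside them. Oligodendrocyte precursor genes lie to the right in both panels (12 and 9 of 14), and matrix and mesenchymal genes to the left (17 and 16 of 19).

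The changes against AG were largely shared between the sites. Of the genes tested, 1241 were called higher and 1652 lower in both comparisons, and 1 gene was called in opposite directions. Lists of these sizes drawn independently would share 263.5 higher and 391.1 lower genes, and 50 simulations of unchanged groups against the same AG libraries gave 0.02 shared calls on average. Across genes, which are not independent replicates, the log2 changes correlated at 0.924, against 0.0812 in the simulations, and 85.9% had the same sign, against 55.1%. The covariance of the changes was 5.22, against 0.0318 in the simulations, a difference of 5.19. The simulated groups had the same mean for each gene, so that the simulations hold only the spread between libraries. Any trait of the AG cells themselves enters both comparisons and is not measured by the simulations. The 3 AG libraries are too few to be split, and part of the excess over independent lists may come from the shared controls. The overlap of 2893 genes fell to 1575, 1559 and 1565 without AG_1, AG_2 or AG_3.

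The comparison of the tumour mean with AG called 2063 genes higher and 2385 lower (4448 in total). Upper-quartile rescaling gave 2616 higher and 1942 lower. The count was 2504 without AG_1, 2504 without AG_2 and 2525 without AG_3. Camera called 11 lists, the same ones that BS showed against AG, 6 higher and 5 lower, and 0 with an estimated correlation.

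The comparison of the tumour sites with each other asks whether OB and BS cells differ. By limma, 0 of 10576 genes passed, 1019 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0545. edgeR on the recovered reads also called 0 genes, and DESeq2 called 233, 163 higher and 70 lower in OB. With the number in the titles as a fixed block limma called 251 genes, a fit that rests on the 2 numbers found in both groups. This fit takes its spread between libraries mainly from AG, which is not part of the comparison and varies less. The median SD of a gene was 0.12 in AG, 0.47 in BS and 0.48 in OB, so that these 251 calls may be too many. The labels do not say what the number marks. Leaving out OB_257 or BS_296 gave 3 calls each, leaving out BS_295 gave 1, leaving out OB_287 gave 67, and leaving out both OB_257 and BS_287, a choice made after the data were seen, gave 63. The groups did not overlap in 9.99% of genes, where chance gives 10%. Without OB_287 the gene of cyclin D1, Ccnd1, was among the calls. With all libraries it had 27296 ± 4742 in BS and 9219 ± 4554 in OB (limma adjusted p = 0.176), and Olig2 23155 ± 8942 and 12141 ± 8478 (limma adjusted p = 0.582).

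By list, mature oligodendrocyte genes were higher in OB as a set, with a median log2 difference of 3.48 over 8 genes (camera adjusted p = 7.6e-05, and adjusted p = 0.485 with an estimated correlation). None of the 8 passed over all genes, and 4 were higher adjusted over the list alone. Myrf stood at 7051 ± 7810.0 in OB and 298 ± 336 in BS (limma adjusted p = 0.234). The libraries of a group differed widely: Myrf had 15866 normalized reads in OB_257 and 4296 in OB_295, but 993 in OB_287, near the 687 of BS_296. A further 5 lists were lower in OB by camera: stem and progenitor genes (median -1.01, camera adjusted p = 0.0129), cholesterol synthesis (-0.35, camera adjusted p = 0.0129), DNA replication (-0.36, camera adjusted p = 0.0129), Hedgehog response genes (-1.41, camera adjusted p = 0.0437) and mitosis genes (-0.25, camera adjusted p = 0.0437). With an estimated correlation their adjusted p was 0.485 for Hedgehog response genes and 0.635 for each of the others. Of the 6 lists, the mature oligodendrocyte list alone was called without BS_295, where the count was 1. There were 3 lists without OB_257 and 3 without OB_295. Each of the 5 lower lists lost its call without at least 1 tumour library: the stem and progenitor list without BS_287, BS_295 or OB_257, DNA replication without BS_295 or OB_257, cholesterol synthesis without BS_295 or OB_295, Hedgehog without any one tumour library except OB_257, and mitosis without BS_295, BS_296, OB_257 or OB_295. Neither the forebrain patterning genes (camera adjusted p = 0.577) nor the hindbrain and Hox genes (camera adjusted p = 0.167, and 0.00283 without BS_287) were called. The other lists were not called by camera in this comparison, the lowest camera adjusted p among them being 0.0599 for RAS-MAPK response genes. Leaving out 1 library called the RAS-MAPK list (without OB_287, 0.00752), the ETS list (without OB_287, 0.035), the interferon list (without BS_296, 0.0393) and the ribosomal list (without BS_296, 0.0249).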

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

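The tests of admixture, of Foxr2 level, of the spread of 2 tumour libraries and of carried-over RNA were chosen after the patterns they address, and most after the values they measure, were seen. The splits of the samples, the thinning of reads and the simulated data were planned before.

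Camera called 6 gene lists as different between OB and BS while limma called 0 single genes (1019 at an unadjusted p under 0.05; edgeR 0, DESeq2 233). Mature oligodendrocyte genes were higher in OB (adjusted p = 7.6e-05). Stem and progenitor genes (0.0129), DNA replication (0.0129), cholesterol synthesis (0.0129), Hedgehog response (0.0437) and mitosis genes (0.0437) were lower in OB. With an estimated correlation 0 lists were called, with adjusted p from 0.485 to 0.635 for these 6. The median difference was 3.48 on the log2 scale for mature oligodendrocyte genes, and it was small for cholesterol synthesis (-0.35), DNA replication (-0.36) and mitosis (-0.25). Cldn11 had 10013, 290.2 and 4243 normalized reads in OB_257, OB_287 and OB_295, and 36.1, 39.5 and 250.2 in BS_287, BS_295 and BS_296.

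For the 0 single genes, all 10 splits of the 6 tumour libraries gave at least as many as the real one, with 28 the highest among the others. A real count of 0 fixes that outcome, so that the splits say nothing here, and splits of 3 against 3 never give a share under 0.1. Leaving out OB_257 and BS_287 together gave 63 genes, but leaving out OB_287 alone gave 67, so that the spread of those 2 libraries was not decided on as a cause. In simulated data with the spread of these libraries, 73.6% of 8-fold changes were called in OB against BS, which lies between the bounds set for that test, so that the number of libraries may also limit the count. A difference between the sites themselves stays open, as does a pairing by the number in the titles, which the main fit leaves out.

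OB_257 and BS_287 lay apart from the other tumour libraries. In OB_257 the cyclin gene Ccnd2 and the receptor gene Egfr had 0 reads, against at least 13308 normalized reads of Ccnd2 in the other tumour libraries. It also had 9440 normalized reads of Trib3 (12.6 to 322 in the other tumour libraries), 143 of Hoxd3 and 259.7 of Hoxd4. BS_287 had 4202 normalized reads of the neuronal factor gene Neurod1, 6946 of Cadm3 and 0 of the imprinted gene Peg3 and of Gpr17. Trib3, the Hoxd genes, Neurod1, Cadm3 and Peg3 are named here after their values were seen. The tables argue against depth as the cause: after thinning all libraries to the lowest total, the gap in correlation was 0.974 of the gap before for OB_257 (0.0883 before, 0.086 after) and 0.983 for BS_287 (0.0542 and 0.0533). A library wholly of cells without Foxr2 overexpression is excluded by Foxr2, at 4505 and 12567 normalized reads, which says nothing about a swap between tumour groups. Mixing in other cells dilutes genes but does not remove them. For OB_257, 10 genes at 500 or more in each of the other 5 tumour libraries were at 5 or less, which argues against admixture as the whole cause, although the bound of 10 genes was set after this result was seen. For BS_287 the number was 5, between the bounds of that test, and the other tumour libraries had 0 such genes. A further test took the share of the common profile left in a library from Foxr2. Under 0.1 times the level this share leaves, beyond counting error, lay 8 abundant genes in BS_287 and 19 in OB_257, and 0 in each of the other tumour libraries. The genes at 5 or less counted above also lie under this level, so that the test in part repeats that count. For BS_287 the share was 1, so that the test only recounts low genes there. It therefore decides nothing for BS_287, and for OB_257 it adds nothing to the earlier count. A smaller share of cells without Foxr2 overexpression, or cells that overexpress Foxr2, stays open in both. Differences between tumours remain a candidate explanation, and no group in the design tests it.

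Hoxa2 to Hoxa5 were present in BS_295, BS_296 and OB_295. Hoxa5 had 662 normalized reads in BS_295, 161 in BS_296, 465 in OB_295, and at most 16.2 in the others. RNA carried over between BS_295 and OB_295 was examined with 4 tests, each after the first chosen once the outcome of the one before was seen. The first test took genes of BS_295 that the other OB libraries lack: their median ratio in OB_295 was 0.509, near the 0.423 to 0.958 of the Hoxa genes, as carry-over would give, but over 3 genes. For 103 genes of OB_295 that BS_287 lacks, whatever their level in BS_296, the median ratio in BS_295 was 0.216. The second counted genes at 500 or more in one library and at 5 or less in the other: 2 of 4353 for BS_295 and 6 of 4469 for OB_295. The third counted genes at 500 or more with a ratio under 0.2: 20 of 4353 and 98 of 4469. Both counts lay between the bounds set for that test. The fourth test asked whether carry-over can be the whole source, since every abundant gene must then reach at least the lowest ratio of the Hoxa genes. From OB_295 to BS_295 that ratio is 1.04, with a lower counting limit of 0.779, and 648 of 4469 genes lay below this limit beyond their own counting error, where at most 2.23 would by chance. From BS_295 to OB_295 it is 0.423, with a limit of 0.289, and 24 of 4353 genes lay below the limit, against 2.18. The tables therefore argue against carry-over as the whole source in either direction. A smaller share of carried-over RNA in either library may remain, as may cells of a like regional origin, which was not tested.

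Some reads outside the tested genes stood out. Y-linked genes, left out of the tests by the filter on low values, had reads in OB_287, with 666.2 normalized reads of Ddx3y, 268.4 of Kdm5d and 16.2 of Eif2s3y, against at most 9.17, 0.83 and 0 in AG. Xist, which was among the tested genes, had 17.6 in BS_287 and 7.61 in OB_287, 1478 to 2079 in AG and 24325 to 33933 in the other tumour libraries. These sex-linked genes thus differed between libraries within each tumour group, and no comparison took that into account. No explanation was tested for these. Transcripts without a gene name took 0.53%, 0.432% and 0.904% of reads in BS_287, BS_295 and BS_296 and 0.793%, 0.446% and 0.483% in OB_257, OB_287 and OB_295, against at most 0.342% in AG. Most of these reads lay in the 45S rRNA transcript, which took 0.178% to 0.326% of reads in AG, 0.405% to 0.890% in BS and 0.418% to 0.755% in OB. Why it was higher in the tumour libraries was not tested.

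Other splits of the samples were run for the comparisons with AG. For OB against AG, 1 of 10 splits of the 6 libraries, the real one, gave as many as 3695 genes, and the highest of the others gave 0. For BS against AG it was 1 of 10 as well, with 3712 genes and 0. With 10 splits the share is never under 0.1. In a fit of 2 groups, the split of 9 libraries into AG and tumour cells gave 4328 genes. Of 84 splits 1, the real one, gave as many, and the highest of the others gave 1. A random grouping of these 9 libraries would thus rarely give that count. The labels do not show separate animals or cultures within a group, so that chance between animals or cultures is not excluded. The split does not separate tumour from strain, genotype or culture.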

How the results depend on the processing

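Transcripts of a gene kept apart, genes with 1 RefSeq transcript only, library weights, the marker list without Foxr2 and the removal of OB_257 together with BS_287 were chosen after the data were seen; the other alternatives were planned.

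The counts against AG stayed within 1.5 times the main count under the pseudocounts, filters, rescalings, trend settings, edgeR, DESeq2, library weights and the removal of both libraries. A test against a 1.5-fold change, stricter by construction, gave 2206 genes for OB against AG, 2147 for BS against AG, 2449 for the tumour mean and 1721 shared genes. With 1 library left out, the counts ran from 2086 to 3719 for OB against AG, from 2001 to 3562 for BS against AG, from 2504 to 4804 for the tumour mean and from 1559 to 3240 for the overlap. Each of the low values came with an AG library left out.

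For OB against BS, where limma called 0 genes, a pseudocount of 0.5 gave 4, a pseudocount of 5 gave 6, quantile normalization 3, variance without a trend 2, DESeq2 233, genes with 1 RefSeq transcript 2, library weights 13 and removal of both libraries 63. With 1 library left out the count ran from 0 to 67 (67 without OB_287). The number in the titles as a fixed block gave 251 genes and as a random effect 4. The fixed block takes its spread between libraries mainly from AG, which is not part of this comparison and varies less. The labels do not say what the number marks, and the values do not settle it. Deviations from the group mean correlated at 0.069 for BS_287 with OB_287 and 0.299 for BS_295 with OB_295, against 0.291 for BS_296 with OB_295. Xist was low in BS_287 and OB_287 alone (17.6 and 7.61), but Ddx3y had 8.39 in BS_287 and 666.2 in OB_287. Hoxa2 to Hoxa5 were high in BS_295 and OB_295, but present in BS_296 too. Nothing is concluded from the block. The cause of the other differences was not tested.

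With an estimated correlation camera called 0 lists in each of the 4 comparisons. The rotation test fry, which does not compare a list with other genes, called 20 for OB against AG, 18 for BS against AG, 1 for OB against BS and 22 for the tumour mean. The 1 list for OB against BS was that of WNT response genes, lower in OB (fry adjusted p = 0.0218, camera adjusted p = 0.0639). None of the 6 lists that camera called between the sites passed fry. Their fry adjusted p ran from 0.0684, for mature oligodendrocyte and Hedgehog genes, to 0.618 for mitosis genes. With genes of 1 RefSeq transcript 6 lists were called for OB against AG, from fewer genes. With 1 library left out, 11 to 13 lists were called for OB against AG, 9 to 13 for BS against AG, 1 to 7 for OB against BS and 10 to 13 for the tumour mean. The mean correlation between libraries of a group was 0.798 in place of 0.934 over the 500 genes of largest variance, which are chosen to vary.

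Of 2313 values of 241 named gene results under alternatives, 2111 kept the call or its absence, 200 lost the call and 2 gained it. In 0 of them did the direction change with a call in either setting. A change of direction where neither value was called counts as kept in these numbers. Leaving out 1 library accounted for 170 of the losses. All 90 values of the 3 design genes kept the call or its absence, which does not hold the direction of the uncalled Trp53 fixed. Of 1127 values of 87 list results, 995 kept the call or its absence, 81 lost the call and 51 gained it. Again 0 changed direction with a call in either setting, while lists called in neither could change direction. Depth limits genes with few reads in AG, where 0 reads allow a normalized value of up to 2.91.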
